A study of Homo sapiens with 27 samples.

How the data were processed

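The authors deposited 2 tables of raw counts, 1 for ribosome footprints and 1 for mRNA reads. Each table gives the authors' count of reads per Ensembl gene with 1 column per library, and no library is pooled or scaled. Both tables hold 20453 genes, of which 20407 have a symbol in the gene name table used here and 46 do not, and 13 symbols belong to more than 1 identifier. Per the submitters' processing notes, STAR 2.7.10a, featureCounts 2.0.1 and DESeq2 1.26.0 were used for both assays and Bowtie2 2.4.5 for the footprints, with the genome build GRCh38/hg38. The role of each tool, the annotation release, the counted feature (whole exons or coding sequence), the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads shared between close paralogs are therefore uncertain, which concerns CCL3 and CCL3L3, CCL4 and CCL4L2, the metallothioneins, the IFIT genes, the HLA genes and the histones, as do reads from genes that overlap on opposite strands.

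Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested 2-sided with the edgeR quasi-likelihood F test. Every adjusted p given for a gene is the Benjamini-Hochberg value from that test over all genes of a comparison, and a gene is called at an adjusted p under 0.05 with no limit on the fold. RNA-seq (12 libraries) and footprints (15 libraries) were fitted separately, each with 3 treatment groups and 1 spread per gene shared by them. Translational efficiency (TE), the footprints per mRNA, was tested as the footprint change minus the RNA change in 1 fit over all 27 libraries. Library scaling makes each of these changes relative to the average gene, so a shift of all genes together could not be seen. Log2 fold changes are edgeR's, computed here from the deposited counts and given with a standard error (SE). Levels are CPM (a gene's counts per 1 M counts of the library), computed here from the deposited counts with TMM-scaled library sizes, and given as mean ± SD.

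Genes were sorted into 4 classes by their 3 tests. Forwarded genes passed in RNA and footprints in the same direction and not in TE. Exclusive genes passed in TE and footprints and not in RNA. Buffered genes passed in TE and RNA with opposite signs. Intensified genes passed in all 3 tests with TE and RNA of the same sign.

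A collection of 27 gene lists, covering 939 genes of macrophage activation, glucocorticoid response, metabolism, translation and cell identity, was compiled from textbook knowledge, and 938 of these genes were found in the tables. Lists with at least 5 tested members were compared with all other genes by limma 3.58.1's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, and the adjusted p of a list is over the lists of 1 comparison. The same test with a correlation estimated from the data was run beside it. For the list's members the text gives the number past the gene-wise test and, in brackets or a clause, the number when adjusted over the list alone. The tests, the lists, the rule for named genes and the alternative settings, apart from those named as chosen later, were fixed before the data were examined.

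The genes named in the text follow that rule. For LPS against vehicle and for LPS+Dex against LPS it takes a panel of well-known targets, plus the 5 genes with the largest rise and the 5 with the largest fall in RNA. These had to have a symbol, pass in RNA and footprints in the same direction, reach a mean of 5 CPM in both assays and show no overlap between the libraries of the compared groups. For TE it takes the 5 largest rises and falls among called genes with a mean of at least 5 CPM in both assays. For each list described it takes the called member with the largest rise and the one with the largest fall. Genes named outside the rule are said to be so. Coordinates are those of GRCh38.p14.

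The labels number the replicates and do not state whether they are separate cultures, so the p-values measure only the spread between these samples. They also do not say whether equal numbers belong together. After the treatment means were removed, footprint libraries of the same number correlated above 0.1 over genes in 15 of 15 pairs (median r = 0.271, range 0.182 to 0.791). The footprint and TE fits were therefore repeated with the replicate number as a block. Pairs of different number also exceeded 0.1 in 34 of 60 cases (median r = 0.1685), so the 15 of 15 alone does not show pairing. Any strong pairing rests on the libraries numbered 4. Without them 3 of 12 pairs of the same number exceeded 0.1 (median r = 0.0455), against 2 of 36 of different number (median r = -0.0165). A weak pairing of the other footprint libraries therefore stays possible. In RNA-seq 7 of 12 pairs of the same number exceeded 0.1 (lowest -0.336), against 13 of 36 of different number. Without the libraries numbered 4 these were 6 of 9 (median r = 0.276) and 5 of 18 (median r = -0.174). Whether RNA numbers pair stays open, and they were not treated as pairs. No 2 libraries of a group were duplicates of each other. In simulated counts drawn with the depth and spread of these libraries and with 2-fold changes planted, the tests of LPS against vehicle recovered 89.8% of planted genes in RNA, 71.2% in footprints and 52.8% in TE. False calls were 15, 9 and 3. Planted were 197 of 13190 tested genes in RNA and 392 of 12060 in footprints, a far smaller share than was called in the real data. As the adjusted p depends on that share, these rates do not give the recovery in the real RNA and footprint comparisons. The list test called the planted list and 0 of 20 random lists. As each gene was drawn independently, this does not show how often the list test errs where genes move together. In other splits of the real libraries it often called lists, as given below.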

Results

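Ribosome profiling, which sequences the mRNA fragments held by ribosomes, and poly(A) RNA-seq were made from THP-1 cells, a human monocytic leukaemia line. The cells were turned into macrophage-like cells with 10 ng/ml of the phorbol ester PMA for 24 h and then treated for 3 h. The 3 treatments were vehicle, 100 ng/ml of lipopolysaccharide (LPS, the bacterial ligand of Toll-like receptor 4), and LPS with 1 µM dexamethasone (LPS+Dex), a synthetic glucocorticoid. No group received dexamethasone alone, so its effect was measured in the presence of LPS only. RNA-seq had 4 replicates per treatment (12 libraries) and ribosome profiling 5 (15 libraries). RNA libraries held 21.8 to 30.7 M counts with vehicle, 20.9 to 24.9 M with LPS and 19 to 21.7 M with LPS+Dex. Footprint libraries held 15.4 to 24.3 M, 20.8 to 26.1 M and 11.5 to 24.4 M in the same order. Between 15430 and 16354 genes had at least 1 count in an RNA library, and between 13805 and 14716 in a footprint library. In all 3 treatments the footprint library numbered 4 stood apart from the others of its group.

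The first comparison, LPS against vehicle, asks how the cells answer to endotoxin in their mRNAs and in what their ribosomes translate. Genes of inflammatory messengers rose in both assays. TNF, the early inflammatory cytokine (ENSG00000232810, chromosome 6, 31575565 to 31578336), went from 53.4 ± 13.4 to 1210 ± 148 CPM in RNA-seq (mean ± SD, n = 4 each), a log2 fold change of 4.5 ± 0.17 (SE). Its footprints rose by 5.96 ± 0.83, from 51.1 ± 23.9 to 3190 ± 3690 CPM (n = 5 each). Without LPS footprint replicate 4 alone that rise was 4.92, and without the 3 libraries numbered 4 it was 5.22, from 41.2 to 1540 CPM. IL6 (ENSG00000136244, chromosome 7, 22727200 to 22731998), a cytokine that drives the acute-phase response, rose by 6.48 ± 0.18 in RNA and 6.96 ± 0.25 in footprints. ACOD1, which makes the antimicrobial metabolite itaconate (chromosome 13, 76948511 to 76958638), rose 635-fold in RNA and 592-fold in footprints, the largest rise among genes that the naming rule admits.

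Other mediators rose in both assays as well. IL1B, the cytokine that inflammasomes activate, rose by 4.26 ± 0.12 in RNA and 4.00 ± 0.47 in footprints. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 5.67 ± 0.31 and 6.74 ± 0.60. The chemokines CXCL10 and CXCL11, which attract T cells, rose by 8.20 ± 0.19 and 7.91 ± 0.29 in RNA and by 7.03 ± 0.52 and 6.35 ± 0.52 in footprints (7.79 and 7.29 without vehicle footprint replicate 4, 7.94 and 7.44 without all 3 libraries numbered 4). IDO1, which breaks down tryptophan, rose by 8.29 ± 0.17 and 7.89 ± 0.29. CXCL8 rose by 3.62 ± 0.12 and 3.61 ± 0.63, CCL3 by 5.11 ± 0.14 and 5.11 ± 0.70, and CCL4L2 by 7.73 ± 0.11 and 7.88 ± 0.27, with the last 2 uncertain because of close paralogs. Without vehicle footprint replicate 4 the footprint values of CXCL8 and CCL3 were 4.29 and 5.78. The NF-kB inhibitors NFKBIA and TNFAIP3 rose by 2.69 ± 0.12 and 2.53 ± 0.09 in RNA and by 2.75 ± 0.11 and 3.18 ± 0.15 in footprints. TLR4, the receptor itself, rose in RNA (0.66 ± 0.19, adjusted p = 0.0085), while its footprint value of 0.94 ± 0.40 did not pass (adjusted p = 0.059). Among genes that the naming rule admits, the largest falls were those of MTUS1, a microtubule-associated protein (-4.51 ± 0.19 in RNA, -4.56 ± 0.24 in footprints), RGS14, a regulator of G protein signalling (-4.17 ± 0.13, -4.83 ± 0.19), GPRIN3 (-3.89 ± 0.44, -3.27 ± 0.49, or -3.9 in footprints without LPS replicate 4), RAB11FIP4, an effector of endosomal Rab11 (-3.65 ± 0.22, -3.42 ± 0.21), and ITPKB, an inositol phosphate kinase (-3.62 ± 0.24, -3.77 ± 0.21).

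**Figure D1:**
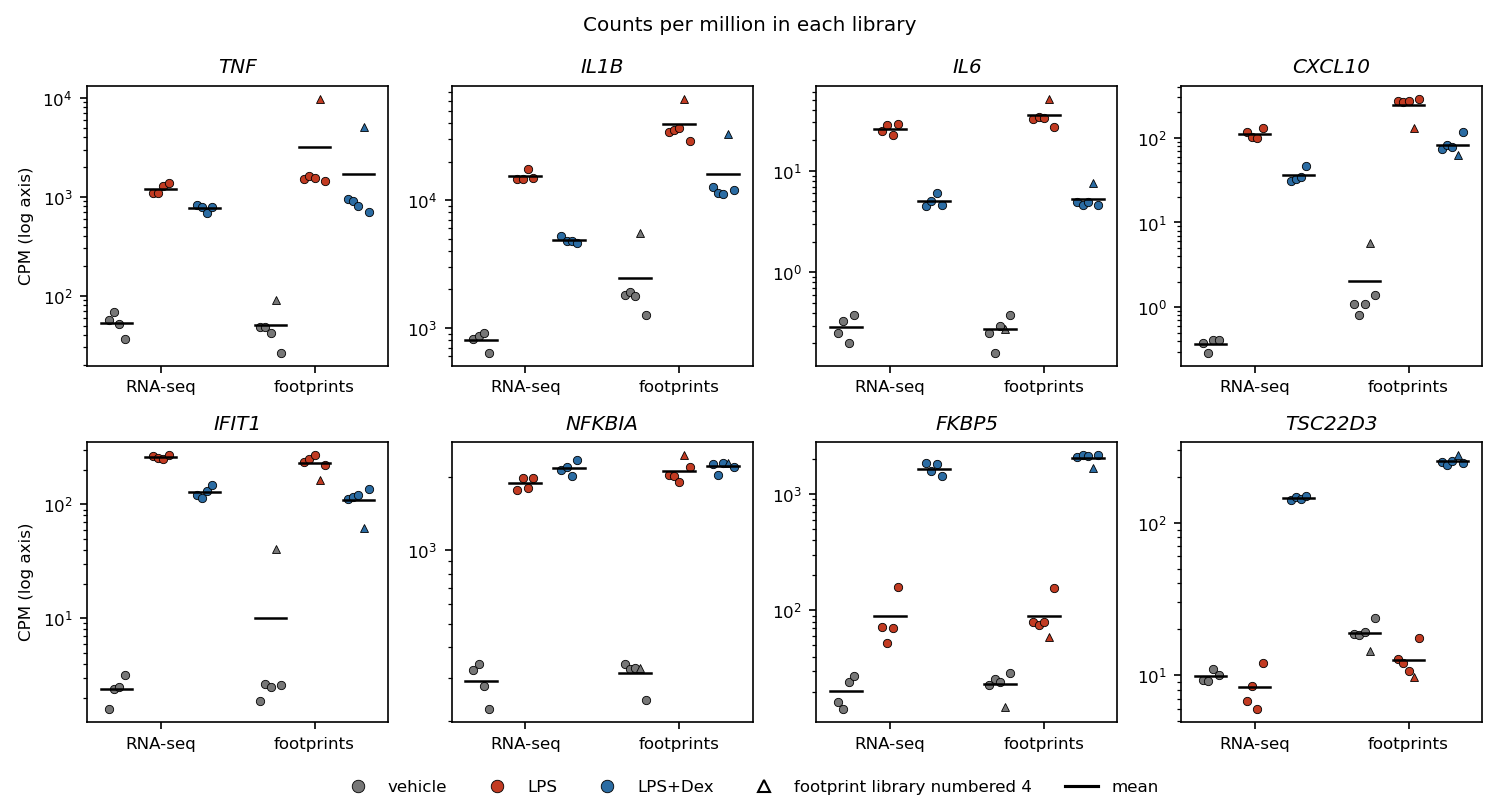
Library-scaled counts (CPM, log axis) of 8 genes in each library, with 4 RNA-seq and 5 footprint libraries per treatment; points are libraries, triangles the footprint libraries numbered 4, and bars the means. FKBP5 in RNA-seq averaged 20.4 CPM with vehicle, 88.7 with LPS and 1660 with LPS+Dex, while TNF averaged 53.4, 1210 and 770.

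Most genes of 3 lists of the inflammatory response rose with LPS. Of 30 tested cytokine and chemokine genes 28 rose in RNA and 0 fell (28 also when adjusted over the list alone; list adjusted p = 4.1e-18), and 26 of 31 rose in footprints (26, and 16 by DESeq2; adjusted p = 1.8e-12, and 0.23 with an estimated correlation). Within this list, which does not hold CXCL10, CXCL11 or CCL4L2, the largest rise was that of CCL8, a monocyte attractant, at 7.68 ± 0.31 in RNA and 4.29 ± 0.78 in footprints (6.62 without vehicle footprint replicate 4, 6.6 without all 3 libraries numbered 4). All 33 tested genes of NF-kB feedback and survival rose in both assays (33 adjusted over the list alone; adjusted p = 1.4e-21 in RNA and 1e-24 in footprints), led by TNIP3, a partner of TNFAIP3, at 6.32 ± 0.21 and 6.01 ± 0.21. Of 41 interferon response genes 41 rose in RNA (41; adjusted p = 7.8e-28) and 39 in footprints (39, and 32 by DESeq2; adjusted p = 3.4e-17, and 0.18 with an estimated correlation). IFIT1, an antiviral RNA sensor, rose 106-fold in RNA, from 2.41 ± 0.647 to 260 ± 8.32 CPM (n = 4). In footprints it rose 23.8-fold, a log2 fold change of 4.57 that vehicle replicate 4 (40.3 CPM) lowers. Without that library it was 6.57, and without all 3 libraries numbered 4 it was 6.66, from 2.4 to 245 CPM, against 6.73 in RNA. In the footprint libraries numbered 4, cytokine genes lay above the other libraries by a median log2 deviation of 1.17 with vehicle and 1.73 with LPS, and interferon genes by 1.54 with vehicle and -0.52 with LPS. With the replicate number as a block 30 cytokine and 41 interferon genes rose in footprints.

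In 4 further lists that passed with LPS more genes rose than fell. MAPK phosphatases and immediate early genes rose in 23 and fell in 3 of 33 in RNA (23 and 3 adjusted over the list alone; adjusted p = 4.5e-06, and 0.19 with an estimated correlation), and rose in 18 and fell in 4 in footprints (18 and 4; adjusted p = 2.6e-05, and 0.22 with an estimated correlation). Within them the nuclear receptor NR4A3 rose by 4.15 ± 0.23 and 4.08 ± 0.22, and FOS, a subunit of AP-1, fell by 1.10 ± 0.28 and 1.73 ± 0.22. Inflammasome and cell death genes rose in 18 and fell in 6 of 29 in both assays (19 and 6 in RNA, 18 and 7 in footprints, adjusted over the list alone; adjusted p = 0.00071 and 0.0039). There the DNA sensor AIM2 rose by 4.98 ± 0.17 and 4.40 ± 0.61 (5.35 in footprints without vehicle replicate 4, 5.58 without all 3 libraries numbered 4), and the sensor adaptor NLRC4 fell by 2.55 ± 0.12 and 3.11 ± 0.21. Heat shock and oxidative stress genes rose in 17 of 26 in both assays, with 4 falling in RNA and 3 in footprints (17 and 4 in both when adjusted over the list alone). This list passed in RNA (adjusted p = 0.011, and 0.49 with an estimated correlation) and in footprints (adjusted p = 4e-04, and 0.084 with an estimated correlation). Its members include the subunits of the enzyme that makes glutathione precursor, of which GCLM rose by 2.01 ± 0.12 and 1.77 ± 0.12 and GCLC fell by 1.5 ± 0.08 and 1.74 ± 0.16. Antigen presentation by MHC rose in 11 and fell in 2 of 21 genes in RNA (11 and 2; adjusted p = 0.025, and 0.49 with an estimated correlation), with the peptide transporter TAP1 up by 2.17 ± 0.09, and did not pass in footprints (3 and 1 of 22, 1 and 1 adjusted over the list alone; adjusted p = 0.58).

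Ribosome biogenesis genes rose with LPS in both assays, and most ribosomal protein genes rose in footprints. Ribosome biogenesis genes rose in 31 of 31 in RNA (31 adjusted over the list alone; adjusted p = 6.7e-11) and in 30 of 31 in footprints (31; adjusted p = 7.5e-15), and the RNA helicase DDX21 rose by 1.36 ± 0.32 and 1.65 ± 0.08. Cytosolic ribosomal protein genes, whose mRNAs carry the 5-prime TOP motif of growth control, rose in 36 of 77 in RNA (20; adjusted p = 3e-05, and 0.68 with an estimated correlation) and in 63 of 72 in footprints (65; adjusted p = 6.6e-15). The other TOP mRNAs of translation factors rose in 18 of 21 in RNA (19; adjusted p = 6.1e-05, and 0.19 with an estimated correlation) and in 21 of 21 in footprints (21; adjusted p = 6.2e-09). RPL21 rose by 1.06 ± 0.20 and 0.92 ± 0.25, and VIM, the intermediate filament vimentin, by 1.27 ± 0.08 and 1.28 ± 0.35. Translation initiation and mTOR genes rose in 20 and fell in 7 of 38 in RNA (20 and 7; adjusted p = 0.027, and 0.23 with an estimated correlation), and in footprints rose in 16 and fell in 8 (16 and 8; adjusted p = 0.11). EIF2AK2, the antiviral kinase PKR, rose by 2.42 ± 0.16 and 1.40 ± 0.20, and the mTOR inhibitor DEPTOR fell by 1.32 ± 0.30 and 1.41 ± 0.33. AU-rich element binding and decay factors passed in footprints, with 14 rising and 2 falling of 27 (14 and 3; adjusted p = 0.033, and 0.42 with an estimated correlation), and this ended without the vehicle footprint library numbered 4 (adjusted p = 0.062). Among them N4BP1, an RNA-degrading interferon target, rose by 1.68 ± 0.07 and 1.39 ± 0.20, and ZFP36L1, a decay factor, fell by 2.34 ± 0.14 and 2.17 ± 0.13.

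Most cell cycle genes fell with LPS. Cell cycle genes fell in 25 and rose in 2 of 30 in RNA (25 and 2 adjusted over the list alone; adjusted p = 1.1e-05, and 0.13 with an estimated correlation) and fell in 24 and rose in 2 in footprints (25 and 2; adjusted p = 0.00011, and 0.42 with an estimated correlation). The mitotic kinase AURKA fell by 2.08 ± 0.10 and 2.08 ± 0.14, whereas the G1 cyclin CCNE2 rose by 1.56 ± 0.19 and 2.34 ± 0.14. Replication-dependent histones, whose mRNAs lack a poly(A) tail, fell in 32 of 37 in footprints (35; adjusted p = 1.4e-07, and 0.26 with an estimated correlation). Poly(A) RNA-seq detected 6 of them well enough to test, 2 of which fell (2; adjusted p = 0.48).

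By the edgeR quasi-likelihood test 8291 of 13327 genes changed in RNA, 3818 higher and 4473 lower, with at least 2-fold changes in 1201 and 1689. In footprints 6416 of 12197 changed, 3102 higher and 3314 lower, with at least 2-fold changes in 1096 and 1342. With the replicate number as a block 8186 changed in footprints, among them 6410 of the 6416 in the same direction, and without the libraries numbered 4 the count was 8262. Log2 fold changes in RNA and footprints correlated with r = 0.925 over 11944 genes, which are not independent replicates. DESeq2 set TNF, CCL3, CCL8 and IFIT1 footprints aside as count outliers and gave them no adjusted p.

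**Figure D2:**
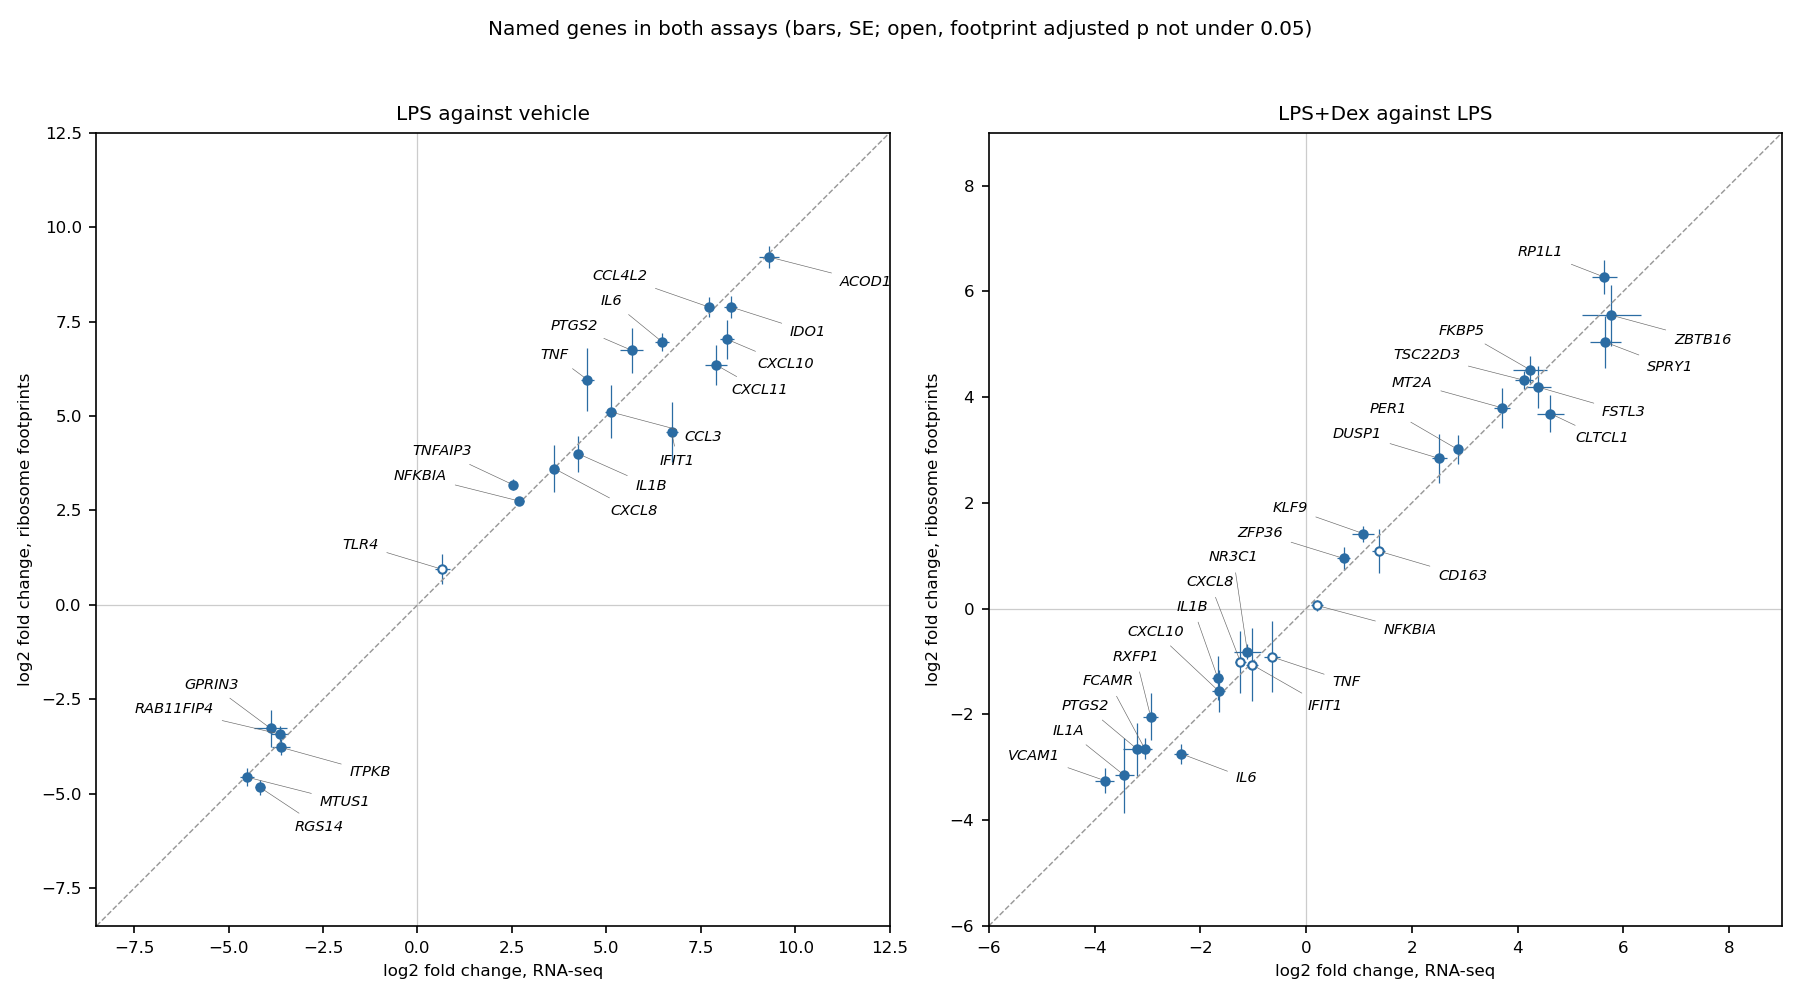
Log2 fold change in RNA-seq (horizontal) and in ribosome footprints (vertical) of the named genes, for LPS against vehicle and for LPS+Dex against LPS; bars are SE, open points did not pass in footprints, and the dashed line marks equal change. With LPS, TNF lies above the line (4.5 in RNA, 5.96 in footprints) and IFIT1 below it (6.73 and 4.57). Without the 3 footprint libraries numbered 4 the footprint values were 5.22 for TNF and 6.66 for IFIT1.

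The second comparison, LPS+Dex against LPS, asks what the glucocorticoid does to this response. Dexamethasone raised 27 of 38 known target genes of its receptor in RNA and 23 in footprints. FKBP5 (ENSG00000096060, chromosome 6, 35573590 to 35728583), a chaperone that restrains the glucocorticoid receptor, went from 88.7 ± 48.1 to 1660 ± 196 CPM in RNA (n = 4) and from 89.5 ± 37.5 to 2050 ± 202 CPM in footprints (n = 5), which are log2 fold changes of 4.23 ± 0.32 and 4.52 ± 0.26. TSC22D3 (GILZ), a mediator of anti-inflammatory action, rose by 4.12 ± 0.17 and 4.32 ± 0.17. DUSP1, a phosphatase that switches off MAP kinases, rose by 2.52 ± 0.14 and 2.84 ± 0.47. In RNA most cytokine and interferon response genes moved the other way, and IL6 fell by 2.37 ± 0.13 in RNA and 2.74 ± 0.19 in footprints.

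Further receptor targets rose in both assays. The clock gene PER1 rose by 2.87 ± 0.08 and 3.01 ± 0.27, the metallothionein MT2A, which has close paralogs, by 3.70 ± 0.15 and 3.80 ± 0.38, KLF9 by 1.08 ± 0.21 and 1.42 ± 0.15, and ZFP36, which destabilises cytokine mRNAs, by 0.71 ± 0.12 and 0.95 ± 0.22. The haemoglobin scavenger receptor CD163 rose in RNA (1.37 ± 0.13), and its footprint value of 1.09 ± 0.42 did not pass (adjusted p = 0.098) until the replicate number was a block (adjusted p = 3.7e-08). NR3C1, the glucocorticoid receptor itself, fell by 1.11 ± 0.25 and 0.81 ± 0.15. Among genes that the naming rule admits, the largest rises were those of ZBTB16, a zinc finger repressor (5.77 ± 0.56 in RNA, 5.55 ± 0.58 in footprints), SPRY1, a brake on growth factor signalling (5.66 ± 0.30, 5.04 ± 0.49), RP1L1 (5.64 ± 0.24, 6.27 ± 0.32), CLTCL1, a clathrin heavy chain (4.62 ± 0.25, 3.69 ± 0.35), and FSTL3, an inhibitor of activin (4.39 ± 0.24, 4.19 ± 0.40). The level of ZBTB16 with LPS came mostly from RNA replicate 4 (35 counts, against 0, 1 and 1) and footprint replicate 5 (75 counts, against 0 to 17). Without these libraries its rises were 9.31 and 6.91, the first resting on 2 counts with LPS, and those of SPRY1 were 6.27 and 5.95. Under the same rule the largest falls were those of the adhesion molecule VCAM1 (-3.81 ± 0.18, -3.25 ± 0.24), the cytokine IL1A (-3.44 ± 0.18, -3.15 ± 0.71), PTGS2 (-3.19 ± 0.27, -2.66 ± 0.50), the immunoglobulin receptor FCAMR (-3.05 ± 0.11, -2.65 ± 0.20) and the relaxin receptor RXFP1 (-2.94 ± 0.14, -2.04 ± 0.45). Footprints of IL1A were -2.3 without LPS replicate 4 and -4.16 without LPS+Dex replicate 4, and those of PTGS2 were -3.3 without the latter.

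The main cytokines fell by different amounts. TNF fell by 0.65 ± 0.15 in RNA (adjusted p = 0.0039), IL1B by 1.67 ± 0.10, CXCL8 by 1.24 ± 0.11, CXCL10 by 1.65 ± 0.12 and IFIT1 by 1.02 ± 0.12. In footprints CXCL10 fell by 1.56 ± 0.40, while the values of TNF (-0.91 ± 0.67, adjusted p = 0.44), CXCL8 (-1.01 ± 0.58, adjusted p = 0.29) and IFIT1 (-1.06 ± 0.69, adjusted p = 0.37) did not pass. Blocking on the replicate number gave adjusted p = 0.0011 for TNF, 1.4e-07 for CXCL8 and 0.14 for IFIT1. Without all 3 libraries numbered 4 these were 4.8e-06, 1e-09 and 3.2e-10. Leaving out the LPS library numbered 4 alone turned TNF to 0.14, and leaving out the LPS+Dex library numbered 4 gave -1.92 (adjusted p = 0.03). Footprints of IL1B fell by 1.31 ± 0.42 (adjusted p = 0.046), and this call ended when any 1 of vehicle 1, 2 or 3, LPS 1, 2, 3 or 4, or LPS+Dex 1, 2, 3 or 5 was left out (adjusted p = 0.05 to 0.1), while the block gave 8.5e-08. NFKBIA did not pass in either assay (0.21 ± 0.11, adjusted p = 0.17, and 0.06 ± 0.11, adjusted p = 0.8).

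Glucocorticoid receptor targets rose in 27 and fell in 5 of 38 in RNA (27 and 5 adjusted over the list alone; adjusted p = 4.3e-11) and rose in 23 and fell in 2 in footprints (25 and 2; adjusted p = 1.2e-15). RGS2, which limits G protein signalling, fell within this list by 1.21 ± 0.12 and 1.42 ± 0.17. Interferon response genes fell in 39 and rose in 0 of 41 in RNA (39; adjusted p = 1.2e-21, and 0.059 with an estimated correlation) and fell in 16 in footprints (26; adjusted p = 4.4e-12, and 0.28 with an estimated correlation). Within this list CXCL9, a T cell attractant, fell the most, by 3.03 ± 0.27 and 2.17 ± 0.33. Cytokine and chemokine genes fell in 23 and rose in 3 of 30 in RNA (24 and 4; adjusted p = 6.3e-10, and 0.059 with an estimated correlation) and fell in 10 of 31 in footprints (13, with 1 rising; adjusted p = 2.3e-06, and 0.58 with an estimated correlation). CSF3, the granulocyte growth factor, rose against the others in RNA (2.37 ± 0.14), with 2.16 ± 0.88 in footprints (adjusted p = 0.12, and 5.4e-10 with the block). Genes of NF-kB feedback and survival fell in 22 and rose in 3 of 33 in RNA (23 and 3; adjusted p = 9.3e-07, and 0.13 with an estimated correlation) and fell in 16 and rose in 4 in footprints (20 and 4; adjusted p = 2.2e-07). IRAK3, an inhibitor of Toll-like receptor signalling, rose there by 1.93 ± 0.08 and 2.28 ± 0.15. With the replicate number as a block 36 interferon and 24 cytokine genes fell in footprints, and without the libraries numbered 4 these counts were 41 and 24. Those libraries lay above the others by a median log2 deviation of 1.73 (LPS) and 2.12 (LPS+Dex) over the cytokine genes.

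Inflammasome and cell death genes fell in 13 and rose in 1 of 29 in RNA (13 and 2 adjusted over the list alone; adjusted p = 0.011, and 0.059 with an estimated correlation) and fell in 10 and rose in 1 in footprints (10 and 4; adjusted p = 0.025, and 0.062 with an estimated correlation). The inflammatory caspase CASP5 fell by 1.62 ± 0.11 and 1.64 ± 0.33. Heat shock and oxidative stress genes fell in 11 and rose in 2 of 26 in footprints (13 and 2; adjusted p = 0.00056, and 0.087 with an estimated correlation), and in RNA fell in 12 and rose in 3 (14 and 4; adjusted p = 0.051). GCLC, which LPS had lowered, rose by 2.04 ± 0.08 and 2.43 ± 0.16. Antigen presentation genes fell in 6 and rose in 1 of 21 in RNA (6 and 1; adjusted p = 0.032, and 0.56 with an estimated correlation). That call ended without RNA LPS replicate 2 (adjusted p = 0.056) or RNA LPS+Dex replicate 1 (0.054), and its largest fall was that of NLRC5, the MHC class I activator, at -0.66 ± 0.10. In footprints 0 of 22 antigen presentation genes passed by edgeR (2 lower at an unadjusted p under 0.05, 0 by DESeq2; adjusted p = 0.41), where the block gave 4 falls. Nuclear-encoded respiratory chain genes rose in 5 and fell in 0 of 70 in RNA (0 and 0; adjusted p = 0.0084, and 0.83 with an estimated correlation). Their largest rise, that of COX5B at 0.47 ± 0.13, was lost without RNA LPS replicate 4 (adjusted p = 0.054) or LPS+Dex replicates 2 (0.05) or 4 (0.052), and mitochondrially encoded mRNAs took a mean of 0.176% of RNA counts with LPS and 0.235% with LPS+Dex.

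Footprints on part of the ribosomal protein mRNAs fell with dexamethasone. Cytosolic ribosomal proteins fell in 19 and rose in 0 of 72 in footprints (34 adjusted over the list alone; adjusted p = 3.7e-11) and in 48 with the block. In RNA 0 of 77 passed by edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2; adjusted p = 0.19). The other TOP mRNAs fell in 8 of 21 in footprints (13; 14 with the block; adjusted p = 6.3e-06), and in RNA 1 of 21 fell by edgeR, VIM by 0.62 ± 0.08, and 3 by DESeq2 (adjusted p = 0.33). Ribosome biogenesis genes fell in 11 and rose in 0 of 31 in RNA (13 and 1; adjusted p = 0.046, and 0.55 with an estimated correlation), a call that ended without RNA LPS replicate 2 (adjusted p = 0.056) or RNA LPS+Dex replicate 4 (0.063). In footprints 5 of 31 fell (7; 11 with the block; adjusted p = 0.00056, and 0.28 with an estimated correlation), and UTP20, a factor of small subunit assembly, fell by 0.47 ± 0.09 in RNA and had -0.27 ± 0.07 in footprints, a call that ended without LPS footprint replicate 3 (adjusted p = 0.054).

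By the same test 4123 of 13327 genes changed in RNA with dexamethasone, 2070 higher and 2053 lower, with at least 2-fold changes in 556 and 539. In footprints 2083 of 12197 changed, 1108 higher and 975 lower, with at least 2-fold changes in 478 and 312. Blocking on the replicate number gave 3769 genes, among them 2080 of the 2083 in the same direction, and leaving out the 3 libraries numbered 4 gave 3855, with 2050 of the 2083. RNA and footprint changes correlated with r = 0.858 over 11944 genes, which are not independent replicates. The list test called 8 lists in RNA, or 15 without RNA LPS+Dex replicate 3, and 9 in footprints, or 14 without footprint LPS replicate 4. With the block the lists of MAPK phosphatases and immediate early genes (adjusted p = 0.022), phagocytic and scavenger receptors (0.048) and LXR targets and lipid handling (0.048) passed in footprints too.

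**Figure D3:**
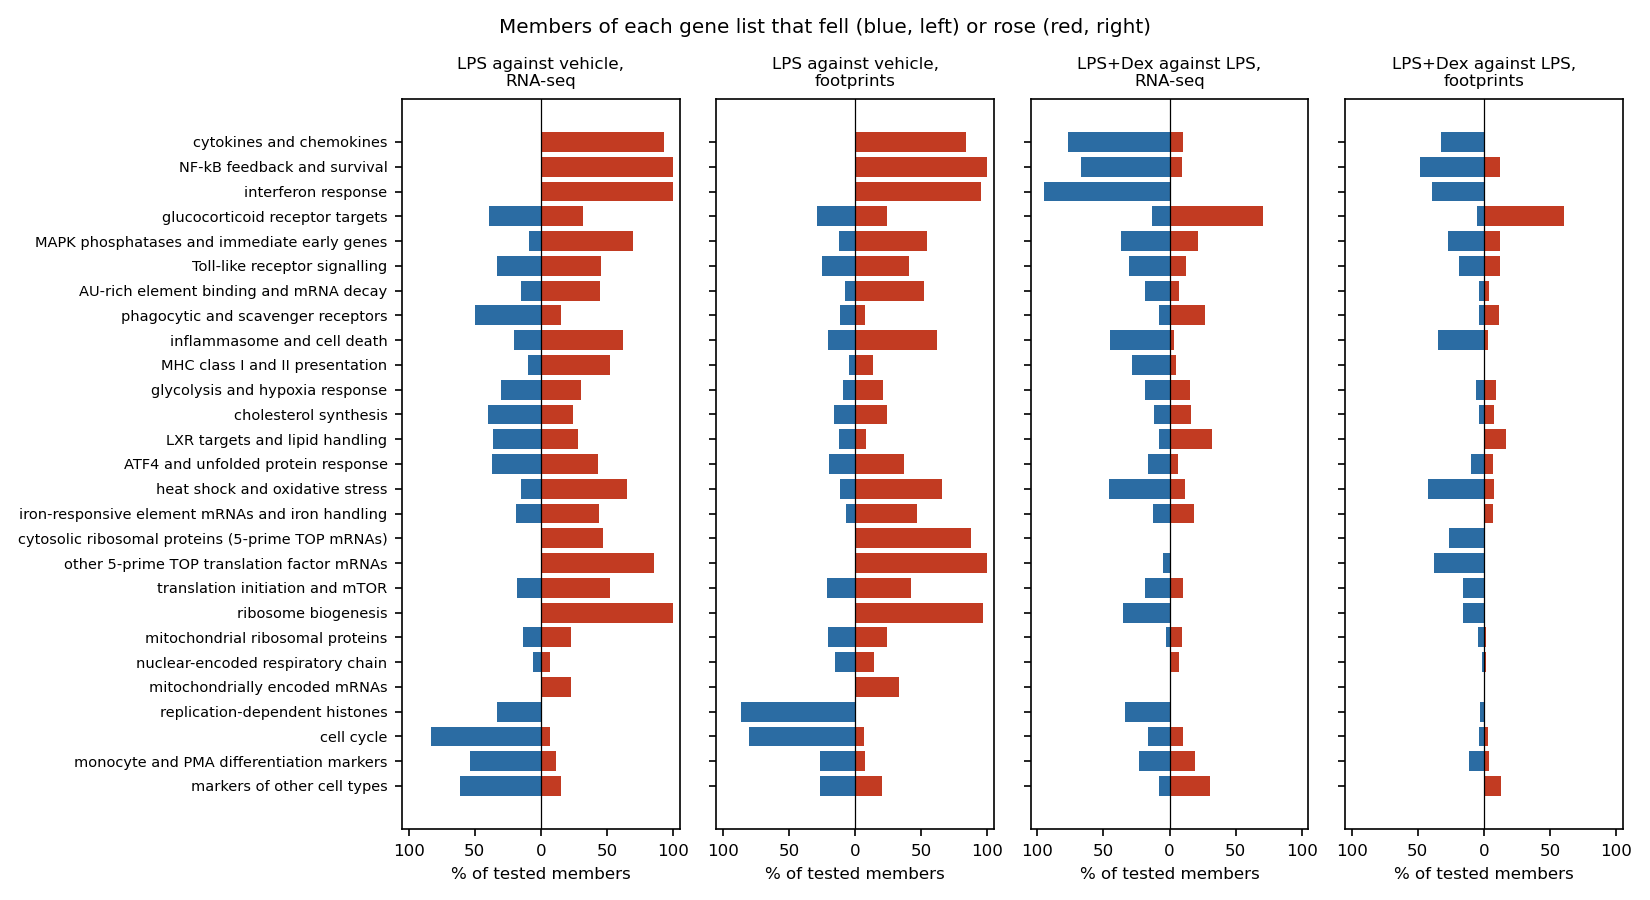
Share of the tested members of each of 27 gene lists (% of members, horizontal) that fell (blue, to the left) or rose (red, to the right) at an adjusted p under 0.05, in RNA-seq and in footprints, with LPS and with dexamethasone. All 33 NF-kB genes rose with LPS in both assays, and 39 of 41 interferon genes fell with dexamethasone in RNA against 16 in footprints.

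Dexamethasone reversed part of the LPS response. In RNA 1328 of the 3818 genes raised by LPS (34.8%) were lowered by dexamethasone, among them IL1B, IL6, CXCL10, PTGS2 and ACOD1, which fell by 2.77 ± 0.17 in RNA. Another 349 were raised further. Of the 4473 genes lowered by LPS, 1192 (26.6%) were raised by dexamethasone, among them GCLC and ZFP36L1, which rose by 1.17 ± 0.13. In footprints 703 of 3102 raised genes (22.7%) were lowered and 610 of 3314 lowered genes (18.4%) were raised. Both comparisons use the same LPS libraries, which alone pushes their errors in opposite directions. Independent lists of these sizes would share 588.2 genes in RNA and 248 in footprints for the first pair, and 694.8 and 301.1 for the second. In 20 simulations that drew the LPS and LPS+Dex libraries from 1 mean, with no dexamethasone effect, the count of raised and lowered genes was 0. The covariance of the log2 fold changes was then -0.0215 in RNA and -0.0366 in footprints, where the real values were -0.2534 and -0.2693. The simulated values leave out the dexamethasone effect, and the independent lists leave out the shared libraries. With separate LPS libraries for each comparison 1043 genes were raised and then lowered in RNA (453.7 for independent lists) and 429 in footprints (126.7). For lowered and then raised genes these were 869 (501.8) and 372 (160.4). Blocking gave 1331 raised and then lowered genes in footprints (34.3% of those raised), and leaving out the libraries numbered 4 gave 1370.

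The comparison of LPS+Dex with vehicle shows how far the reversal went. The naming rule takes more genes than this text names, and of the 46 it takes that LPS raised and dexamethasone lowered in RNA, 33 stayed higher than with vehicle, 7 did not pass and 6 were lower (19, 6 and 1 of 26 in footprints). Of the 24 it takes that LPS lowered and dexamethasone raised in RNA, 10 stayed lower, 5 did not pass and 9 were higher (6, 3 and 5 of 14 in footprints). Among all 1328 raised and lowered genes in RNA, 738 stayed higher, 486 did not pass and 104 were lower (427, 257 and 19 of 703 in footprints). Among all 1192 lowered and raised genes in RNA, 519 stayed lower, 517 did not pass and 156 were higher (229, 293 and 88 of 610 in footprints). The naming rule favours large changes with dexamethasone, so its shares do not stand for all genes. VCAM1 went from 2.33 to 30.5 and then 2.18 CPM in RNA, and FCAMR (9.13, 29.4 and 3.55 CPM), RXFP1 (5.22, 23.7 and 3.09 CPM) and TLR4 (41.5, 65.7 and 18.3 CPM) ended lower than with vehicle. IL6 stayed higher than with vehicle by 4.11 ± 0.20 in RNA and 4.22 ± 0.25 in footprints, and TNF by 3.85 ± 0.17 and 5.05 ± 0.79. CXCL10 stayed higher by 6.56 ± 0.19 and 5.46 ± 0.49, ACOD1 by 6.53 ± 0.28 and 6.64 ± 0.26, and PTGS2 by 2.47 ± 0.29 and 4.08 ± 0.53. Footprints of TNF and PTGS2 were higher by 4.05 and 3.45 without LPS+Dex replicate 4, and those of CXCL10 by 6.23 without vehicle replicate 4. Without all 3 libraries numbered 4, TNF was at 4.36 and CXCL10 at 6.3. NFKBIA was higher by 2.90 ± 0.12 and 2.81 ± 0.11, and FKBP5 by 6.35 ± 0.36 and 6.46 ± 0.29. CD14, the co-receptor for LPS, stayed lower by 1.90 ± 0.15 and 1.71 ± 0.17. In all 8021 genes differed from vehicle in RNA, 3893 higher and 4128 lower, and 5657 in footprints, 2971 higher and 2686 lower. With the block 7454 differed in footprints, among them 5648 of the 5657.

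Translational efficiency asks whether footprints changed more or less than the mRNA. Among called genes with a mean of at least 5 CPM in both assays, it rose most with LPS for TTN, the giant muscle protein titin (TE log2 change 3.33 ± 0.55, adjusted p = 0.0012), whose RNA did not pass (-0.03 ± 0.08) and whose footprints rose by 3.30 ± 0.50. TTN is 1 of 17 heart muscle markers that all rose in footprints, of which 3 rose in RNA and 9 were too low there to test. SPARCL1, a matrix protein, gained 2.66 ± 0.31 in TE while its RNA fell by 1.74 ± 0.14. SGPP2, a sphingosine phosphate phosphatase, gained 2.62 ± 0.30, FSTL3 gained 2.32 ± 0.51 and NCOA7, an oxidation resistance protein, 1.96 ± 0.23. NFKBIZ, a nuclear co-activator of NF-kB targets such as IL6, gained 1.29 ± 0.19, so that its RNA rose 6.36-fold and its footprints 15.7-fold. Under the same limit the largest falls in TE were those of interferon-induced TRIM22 (-2.90 ± 0.64), SAMD9L (-1.92 ± 0.44) and HELZ2 (-1.69 ± 0.39), whose RNA rose by 4.37 ± 0.15, 3.46 ± 0.09 and 2.48 ± 0.10. Without vehicle footprint replicate 4 the TE of TRIM22 was -1.8 and that of SAMD9L -1.22, and without all 3 libraries numbered 4 they were -1.95 and -1.26, with HELZ2 at -1.45. CDCA4 lost 1.47 ± 0.17. IRF7, a master regulator of interferon genes, lost 1.36 ± 0.36 (adjusted p = 0.044), a call that ended when any 1 RNA library of vehicle or LPS, RNA LPS+Dex 2 or 3, footprint vehicle 4 or 5, or footprint LPS 1, 2, 3 or 5 was left out (adjusted p = 0.05 to 0.1).

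Among lists, NF-kB genes gained TE in 4 of 33 (7 adjusted over the list alone; adjusted p = 0.00023, and 0.22 with an estimated correlation), with a median of 0.165. That median was 0.104 without RNA vehicle replicate 3, 0.061 without LPS footprint replicate 4 and 0.032 without all 3 footprint libraries numbered 4. Interferon genes lost TE in 3 of 41 (17; adjusted p = 7.2e-08, and 0.7 with an estimated correlation), with a median of -1.04, which was -0.444 without vehicle footprint replicate 4, or -0.371 with 12 losing and 1 gaining TE once the footprint libraries numbered 4 were left out. With the block 11 lost TE. Cytosolic ribosomal proteins gained TE in 2 of 72 (11; adjusted p = 5.1e-12, and 0.7 with an estimated correlation) with a median of 0.28, and in 17 with the block. That median was 0.172 without RNA vehicle replicate 2 and 0.081 without the 4 RNA libraries lowest on the third principal component. Other TOP mRNAs gained in 3 of 21 (10; adjusted p = 8.4e-10) with a median of 0.26, and in 10 with the block, and the elongation factor EEF1B2 gained 0.67 ± 0.14. Phagocytic and scavenger receptors passed as a list (1 of 25 gained, STAB1 at 1.58 ± 0.25; 1 adjusted over the list alone; adjusted p = 0.0037, and 0.87 with an estimated correlation), which ended without LPS footprint replicate 4 (adjusted p = 0.24). Toll-like receptor signalling (5 of 32 lost TE; 5; adjusted p = 0.044, and 0.22 with an estimated correlation) did not pass with the block (0.092), nor without RNA vehicle 1 or 2, RNA LPS 3 or 4, any footprint library of vehicle 1 to 3, of LPS other than replicate 3, or of LPS+Dex (adjusted p = 0.052 to 0.12). Mitochondrial ribosomal proteins had 0 of 74 past the edgeR gene-wise test (0 adjusted over the list alone; 7 lower at an unadjusted p under 0.05 and 1 by DESeq2; adjusted p = 0.032, and 0.87 with an estimated correlation). That call ended without RNA vehicle 3 or 4, RNA LPS 2, footprint vehicle 1, 2, 3 or 5, LPS 4 or 5, or LPS+Dex 2 (adjusted p = 0.051 to 0.76).

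With dexamethasone 5 genes gained TE. FBXW7, which marks cyclin E and MYC for destruction (chromosome 4, 152320544 to 152536092), gained 2.09 ± 0.33 (adjusted p = 0.0062), with RNA at 0.13 ± 0.10 and footprints up by 2.22 ± 0.30. OGT, which attaches O-GlcNAc to proteins, gained 0.59 ± 0.11 (adjusted p = 0.025) as its RNA fell by 0.42 ± 0.07. Its call ended without any 1 of the RNA LPS libraries, RNA LPS+Dex 1, 3 or 4, footprint LPS 5, or footprint LPS+Dex 1, 2 or 3 (adjusted p = 0.052 to 0.082). The other 3, of too low a level for the naming rule and named after their values were seen, were MTMR7 (4.61 ± 0.47, adjusted p = 3.83e-05), SERHL2 (2.30 ± 0.31, 0.000558) and SEMA6A (1.49 ± 0.25, 0.0131). No gene lost TE by edgeR with TMM scaling on all libraries and without a block, where 383 genes gained and 288 lost TE at an unadjusted p under 0.05. With the replicate number as a block 38 genes gained and 27 lost TE. Without the footprint libraries numbered 4 these were 30 and 23. With RLE size factors 7 gained and 2 lost TE, and with DESeq2 19 and 7. The lists called with dexamethasone all went down without a single member past the edgeR gene-wise test. Cytosolic ribosomal proteins had a median of -0.37 over 72 genes (0 adjusted over the list alone; 34 lower at an unadjusted p under 0.05, 0 by DESeq2; adjusted p = 1e-31, and 0.25 with an estimated correlation). Other TOP mRNAs had -0.20 (1; 5 and 0; adjusted p = 1.2e-08). Nuclear-encoded respiratory chain genes had -0.25 (0; 10 and 0; adjusted p = 3.2e-18, and 0.3 with an estimated correlation), mitochondrial ribosomal proteins -0.10 (0; 3 and 0; adjusted p = 8e-06, and 0.98) and mitochondrially encoded mRNAs -0.60 (0; 1 and 0; adjusted p = 0.0021, and 0.46), or -0.385 without LPS+Dex footprint replicate 1. Mitochondrially encoded mRNAs took a mean of 0.0013% of footprint counts with LPS and 0.00123% with LPS+Dex, so their TE value rests on few counts. The list count was 10 without LPS+Dex footprint replicate 4.

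Forwarded genes, whose footprints changed in the direction of their mRNA, were the largest of the 4 classes. With LPS 5137 of 11944 genes were forwarded, 137 buffered, 68 intensified and 39 exclusive to translation, and with dexamethasone 1643, 1, 1 and 3. The other 6563 genes with LPS and 10296 with dexamethasone fell in no class. In all 244 genes changed in TE with LPS, 114 higher and 130 lower, and 207 between LPS+Dex and vehicle, 123 higher and 84 lower. Blocking on the replicate number raised the TE counts to 930 with LPS, 65 with dexamethasone and 1467 for LPS+Dex against vehicle, which hold all of the 244, 5 and 207. Without the footprint libraries numbered 4 they were 736, 53 and 1064. For the classes with LPS blocking gave 513 buffered, 267 intensified and 150 exclusive genes, and with dexamethasone 2754 forwarded, 45 buffered, 6 intensified and 14 exclusive genes. Leaving out 1 library moved the TE count with LPS to 147 (RNA LPS 1) or 155 (RNA LPS 2). It moved the count for LPS+Dex against vehicle to 119 (RNA vehicle 4), 120 (RNA LPS+Dex 2), 134 (RNA LPS+Dex 4) or 319 (footprint vehicle 4), and the count with dexamethasone to 3 (RNA LPS+Dex 1), 8 (footprint LPS 3), 9 (RNA vehicle 1), 10 (footprint vehicle 4), 11 (RNA vehicle 3) or 14 (footprint LPS+Dex 4). The exclusive class with LPS went to 25 or 23 without footprint vehicle 1 or 5, and the buffered class to 90 or 81 without RNA vehicle 4 or RNA LPS 1. The intensified class went to 37 or 35 without RNA LPS 1 or 2, to 40 without footprint vehicle 1 or 5 and to 108 without footprint vehicle 4. The buffered class with dexamethasone, 1 gene, became 0 without RNA LPS 1 or 3, RNA LPS+Dex 1, 3 or 4, footprint LPS 5, or footprint LPS+Dex 1, 2 or 3. It became 2 without footprint LPS 2 or 4, 3 without RNA vehicle 2 or 4 or footprint LPS 3, 5 without RNA vehicle 1 or footprint vehicle 4, 7 without RNA vehicle 3 and 9 without footprint LPS+Dex 4.

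Transcripts of heart muscle were present in the footprint libraries and moved with LPS. All 17 heart muscle markers that could be tested in footprints rose with LPS. Among them TTN, MYBPC3 and TCAP count among the exclusive genes, and MYOM1 and TNNI3 among the buffered genes. In RNA 3 of the 17 rose, 2 fell, 3 did not pass and 9 were too low to test. Summed over 26 markers, heart transcripts took 47.2 ± 10.1, 288 ± 156 and 176 ± 61.5 CPM of footprints with vehicle, LPS and LPS+Dex (n = 5) and 180 ± 18.4, 246 ± 12.1 and 246 ± 16.1 CPM of RNA (n = 4). The sum holds ACTN2, XIRP1 and ANKRD1, which rose with LPS in RNA too, so it does not give the course of each marker. Footprints of MYH7, named after its values were seen, were 0.444 to 3.87 CPM with vehicle, 7.65 to 102 with LPS and 1.67 to 7.11 with LPS+Dex. Summed liver markers took 23.2 ± 11.3, 32.1 ± 19 and 67.8 ± 68.6 CPM of footprints, the last being 40.3 without LPS+Dex replicate 5. In RNA-seq 8 of the 26 heart and 4 of the 20 liver markers reached 1 CPM.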

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

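For the pattern weighed here the tests of depth and of secreted and membrane proteins were chosen only after the result was seen. A gap test within groups of libraries, over 54 groups, singled out 14 values that lie far from the others of their group. Chance singles out about 1 in 20 groups. Of the 14, 13 were in footprints and 11 in the footprint libraries numbered 4. With LPS the library numbered 4 held 9780 CPM of TNF (1440 to 1630 in the others), 62300 CPM of IL1B (28800 to 36400), 51.3 CPM of IL6 (27.2 to 33.6) and 129 CPM of CXCL10 (265 to 288). With LPS+Dex it held 5100 CPM of TNF (704 to 955), 32800 CPM of IL1B (11300 to 12600), 7.53 CPM of IL6 (4.61 to 4.96) and 1690 CPM of FKBP5 (2080 to 2170). With vehicle it held 5570 CPM of IL1B (1260 to 1910), 5.78 CPM of CXCL10 (0.806 to 1.39) and 40.3 CPM of IFIT1 (1.88 to 2.66). Outside these libraries, NFKBIA was 243 CPM in vehicle footprint replicate 5 (326 to 342), FKBP5 was 155 CPM in LPS footprint replicate 5 (58.6 to 79.7), and IL1B was 17500 CPM in LPS RNA replicate 3 (14600 to 14800).

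The footprint libraries numbered 4 deviated from their groups together, with correlations over genes of 0.793, 0.785 and 0.908 between the 3 treatments (genes are not independent replicates). Depth is argued against because the library numbered 4 lay outside the range of the others in 1 treatment of 3, and a few abundant genes because the lowest correlation was 0.774 after the 89 most abundant genes were left out. A culture shared with the RNA-seq library of the same number is not seen either, as the largest correlation of their deviations was 0.062. Better recovery of mRNAs of secreted and membrane proteins would leave interferon response genes without chemokines and TNFSF10 in place. The mRNAs of secreted and membrane proteins lay above the others by a median of 0.98, 1.55 and 1.64 log2 units with vehicle, LPS and LPS+Dex. Those interferon genes lay at 1.6, -0.5 and -0.03, which argues against better recovery as the whole cause with vehicle. The bound of the test covered upward deviation only, so it does not weigh the -0.5 with LPS. There 10 of 36 interferon genes lay above 0, a lowering that better recovery alone would not give. With LPS it may still underlie the rise of secreted and membrane mRNAs, and with LPS+Dex the pattern. A culture in another state of activation or differentiation, which was not tested, stays open throughout.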

How the results depend on the processing

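The alternatives that leave out the 3 footprint libraries numbered 4, or the 4 RNA libraries lowest on the third principal component, were chosen only after the result was seen. Library sizes without mitochondrial genes and fits over the 2 compared groups left all counts of genes within 1.5 times, as did voom with quality weights for TE and leaving out those 4 RNA libraries (8966, 5930 and 9031 genes in RNA). For named genes, 4478 of the values with 1 library left out kept their side of the threshold and direction, 185 lost and 22 gained a call. DESeq2 kept 314, lost 7 and gained 4. The cause of the shifts below was not tested, except where a stricter limit or fewer libraries makes it plain. A fold of at least 2 left 2890, 1095 and 2595 genes in RNA and 2438, 790 and 1977 in footprints (LPS against vehicle, LPS+Dex against LPS, LPS+Dex against vehicle), and 102 and 103 in TE for the first and last. With the replicate number as a block, footprints gave 3769 genes with dexamethasone and 1331 reversed genes, and TE gave 930, 65 and 1467. Classes with LPS were then 150 exclusive, 513 buffered and 267 intensified, and with dexamethasone 2754 forwarded, 14 exclusive, 45 buffered and 6 intensified. Without the libraries numbered 4 the same results were 3855, 1370, 736, 53 and 1064, then 110, 394 and 232, and 2606, 11, 36 and 6. In RNA, where it stays open whether numbers pair, the block gave 8847, 4858 and 8592. DESeq2 gave 457, 26 and 494 genes in TE, 72 exclusive, 256 buffered and 129 intensified with LPS, and 7 exclusive and 18 buffered with dexamethasone. RLE size factors gave 9 genes in TE and 5 buffered with dexamethasone, footprint replicates 1 to 4 alone gave 3 and 0, and no filter on low counts gave 0 buffered. Lists called with LPS and with dexamethasone were 5 and 1 in RNA, 5 and 4 in footprints and 1 and 1 in TE with an estimated correlation, and with fry 22 and 15 in RNA and 2 and 1 in TE.

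With 1 library left out, RNA counts were 7727 to 8330, 3304 to 4565 and 7333 to 8195, footprint counts 5959 to 6892, 1748 to 2370 and 5094 to 6044, and TE counts 147 to 334, 3 to 14 and 119 to 319. Reversed genes were 1093 to 1467 in RNA and 571 to 845 in footprints. Classes with LPS were 4908 to 5403 forwarded, 23 to 51 exclusive, 81 to 194 buffered and 35 to 108 intensified, and with dexamethasone 1427 to 1816, 2 to 4, 0 to 9 and 1. Called lists were 12 and 7 to 15 in RNA, 11 to 12 and 9 to 14 in footprints, and 5 to 8 and 5 to 10 in TE. Some values that had not passed turned their sign. TTN in RNA with LPS went from -0.03 to 0.01 with DESeq2 and with RLE and to 0.06 without RNA vehicle replicate 2 (lowest -0.09). TNF footprints with dexamethasone were 0.14 without LPS replicate 4 (lowest -1.92). With LPS, footprints of DCN were -0.14 without LPS replicate 1 (highest 0.56) and those of PAN2 -0.01 without vehicle replicate 4 (highest 0.12). Footprints of NLRC5 with dexamethasone were 0.04 without the libraries numbered 4, and 0.06 and 0.07 without LPS replicates 4 and 5 (lowest -0.15). Those of TUBB3 were 0.07, 0.14, 0.01 and 0.04 without LPS 1, LPS 2, LPS+Dex 1 and LPS+Dex 5 (lowest -0.39). Depth limits which genes can be tested, as 13327 of 20453 genes in RNA and 12197 in footprints passed the filter on low counts.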

Other observations

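The tests of splits, of heart induction, of heart markers under 1 CPM, of short transcripts and of the footprint libraries numbered 4 were chosen only after the results were seen. Several lists changed in both directions with LPS and were not called. Glucocorticoid receptor targets rose in 12 and fell in 15 of 38 in RNA (12 and 16 adjusted over the list alone; adjusted p = 0.53), and the adenosine receptor ADORA3 fell by 4.56 ± 0.16 in RNA and 4.61 ± 0.44 in footprints. Toll-like receptor signalling rose in 15 and fell in 11 of 33 in RNA (16 and 11; adjusted p = 0.15), with the ubiquitin ligase PELI1 up by 4.36 ± 0.10 and the co-receptor CD14 down by 2.06 ± 0.15. Phagocytic and scavenger receptors fell in 13 and rose in 4 of 26 in RNA (13 and 4; adjusted p = 0.11). Glycolysis and hypoxia genes rose in 10 and fell in 10 of 33 in RNA (10 and 10; adjusted p = 0.74), and PFKFB4, a regulator of glycolytic flux, fell by 1.52 ± 0.08 in RNA and 2.47 ± 0.16 in footprints. Genes of cholesterol synthesis rose in 6 and fell in 10 of 25 (6 and 10; adjusted p = 0.84), LXR targets and lipid handling rose in 7 and fell in 9 of 25 (7 and 9; adjusted p = 0.84), and ATF4 and unfolded protein response rose in 13 and fell in 11 of 30 (14 and 11; adjusted p = 0.32). Within them the lipid carrier STARD4 rose by 2.4 ± 0.18, PPARG, a lipid-sensing nuclear receptor, fell by 1.78 ± 0.10, and CHAC1, which degrades glutathione, rose by 2.32 ± 0.13. Iron handling rose in 7 and fell in 3 of 16 (7 and 3; adjusted p = 0.28), mitochondrial ribosomal proteins rose in 17 and fell in 10 of 74 (16 and 10; adjusted p = 0.2), the respiratory chain rose in 5 and fell in 4 of 70 (4 and 3; adjusted p = 0.57) and mitochondrially encoded mRNAs rose in 3 of 13 (0; adjusted p = 0.11). Monocyte and PMA differentiation markers fell in 14 and rose in 3 of 26 (14 and 3; adjusted p = 0.11), with the fractalkine receptor CX3CR1 down by 3.12 ± 0.36 and the hyaluronan receptor CD44 up by 3.62 ± 0.10. Markers of other cell types rose in 2 and fell in 8 of 13 (2 and 9; adjusted p = 0.11).

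With dexamethasone, uncalled lists held single genes with large changes in both assays. EGLN1, a sensor of oxygen, rose by 3.74 ± 0.23 in RNA and 3.84 ± 0.18 in footprints, and C1QB rose by 4.06 ± 0.32 and 3.84 ± 0.49. The transcription factor KLF4 rose by 2.21 ± 0.10 and 2.21 ± 0.31 and EGR2 fell by 2.39 ± 0.12 and 2.11 ± 0.24. TLR2, which senses bacterial lipoproteins, rose by 1.67 ± 0.09 and 1.73 ± 0.37, and the kinase MAP2K6 fell by 2.45 ± 0.35 and 2.02 ± 0.49 (-2.67 in footprints without the 3 libraries numbered 4). Thrombospondin THBS1 rose by 3.10 ± 0.23 and 4.05 ± 0.44 (3.33 without LPS+Dex footprint replicate 4), and HERPUD1, a factor of protein degradation at the endoplasmic reticulum, by 1.44 ± 0.06 and 1.5 ± 0.12. FKBP5, chosen after its values were seen, was 160 CPM in LPS RNA replicate 4 (52.9 to 71.8 in the other 3), and in the same library TSC22D3 was 12 CPM (6 to 8.52).

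In LPS footprint replicate 1 there were 2410 counts of MYH7, 4203 of TTN, 913 of ACTA1 and 493 of DES, and albumin (ALB) reached 1201 counts in LPS+Dex footprint replicate 5. The 12 RNA libraries held 0 to 3 counts of MYH7 and 0 to 1 of DES, but 1797 to 3916 of TTN, 29 to 72 of ACTA1 and 64 to 180 of ALB (8 of 26 heart and 4 of 20 liver markers reached 1 CPM in RNA). Induction of the heart muscle mRNAs by LPS was put to 4 tests, all chosen after values were seen. The first 2 decided nothing (log2 ratios of summed markers of 0.45 in RNA and 2.61 in footprints, and 3 rises among the 8 of 17 markers testable in RNA). In the third, the other 9 markers had a median log2 ratio of footprint CPM to the upper limit of RNA CPM of 4.38 with LPS (lower quartile 3.39, where the top 1% of all genes starts at 3.03). These 9 were picked as raised in footprints and too low in RNA, unlike the genes compared, so a high ratio was partly fixed and decides nothing. They held 0 to 26 counts each over the LPS RNA libraries, so little of their mRNA was seen there. The fourth test argues against induction as the whole cause for the 8, whose median RNA change was -0.15 (SD 1.8) against 2.96 in footprints. With vehicle, RNA of TTN (103 to 141 CPM) and MYBPC3 (19.4 to 31.3) far exceeded their footprints (5.7 to 15.8 and 0.0951 to 0.977). A rise of the translated mRNA may not show against such a level, so the test is weaker for TTN and MYBPC3. However, ACTN2, XIRP1 and ANKRD1 rose in both, so induction stays open for these 3, and the tests leave it open for the 9. RNA of heart tissue would bring the same mixture of transcripts into each library. The skeletal muscle excess was 7.6% of that of heart, with skeletal markers at a mean of 13.2 CPM of footprints with LPS, 6.07 without LPS replicate 1 and 5.8 with vehicle. All 26 heart markers were in excess over vehicle both in replicate 1 and in the other LPS libraries, with a correlation of 0.884 (0.876 over those under 1 CPM in RNA-seq). Both excesses subtract the same vehicle libraries and come from 1 treatment, so induction would give such values too and they decide nothing here (the correlations also miss the 0.9 set for the first test), and tissue RNA may be the source but stays open, as does any biological explanation beyond induction, which was not tested.

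The TE of ribosomal protein mRNAs, whose median rose by 0.277 with LPS and fell by 0.368 with dexamethasone, was weighed as well. The rise depended on the 4 RNA libraries lowest on the third principal component (vehicle 1 and 2, LPS 2 and LPS+Dex 4), as the median was 0.081 without them. The fall did not depend on them, as it was then -0.426. Lower RNA quality in single libraries was the explanation put to this test. No quality value per library was available to tie it to that component, so it stays open for both. A property of all short mRNAs is argued against for the rise, since respiratory chain mRNAs had a median of 0.003, and stays open for the fall, where they had -0.249. The footprint libraries numbered 4 are argued against as the source of either, as the medians were 0.288 and -0.363 without them. Control of TOP mRNAs by growth signalling is a candidate explanation that no group of the design tests.

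Other splits of the libraries were used to ask where chance can be excluded. A split that mixes the treatments turns their effect into spread within its groups. Its gene count may therefore understate what chance alone would give. For RNA-seq only the real split of 35, 1 of 35 and the lowest share possible, gave as many genes as the 8291, 4123 and 8021 of the 3 comparisons, and the highest other count was 0. The 1328 reversed genes were reached by the same 1 split (highest other 0), which adds nothing, since no other split called any gene to be reversed. In footprints the real split was also the 1 of 100 that reached 6416, 2083, 5657 and 703, where the highest others were 2027, 246, 1045 and 57. Among splits that part all 5 pairs of footprint replicate numbers, as the real one does, the highest others were 0, 0, 1 and 0. For TE with LPS 5 of 100 splits reached 244 genes (highest other 6352). Of the 4 others 2 keep the footprint libraries of each treatment together and 2 do so for all but 1 library of each. The RNA libraries are mixed, but in the splits with 6352, 2765 and 1586 genes most lie on the side opposite to the footprints. These splits call many times the real count and point to a structure of the samples. They carry the LPS effect of the footprints and in part that of RNA with the opposite sign. They therefore do not show whether chance can be excluded. The 1 other split that parts all 9 pairs of equal number gave 0 genes and 0 exclusive genes. For TE with dexamethasone 4 of 100 reached 5 genes (highest other 1929), and the 3 others keep all footprint libraries (2) or all RNA libraries (1) of a treatment together, so the same holds. Among the 4 others that part all 9 pairs 1 gave 100 exclusive genes and slightly more TE genes, both far above the real 3 and 5. For exclusive genes these splits do not show it either, as 3 of 100 reached 39 with LPS and 3 with dexamethasone (highest others 5612 and 1689), and the others keep all footprint libraries together. The 207 TE genes of LPS+Dex against vehicle were reached by 1 split (highest other 41), as were the forwarded, buffered and intensified genes with LPS (5137, 137 and 68; highest other 0) and the forwarded and intensified genes with dexamethasone (1643 and 1; highest other 0). As these classes need genes that pass in RNA, few of which other splits give, their counts add little to those for RNA. The 1 buffered gene with dexamethasone was reached by 2 splits (highest other 11). The numbers of called lists were reached often. In RNA 15 of 35 splits gave the 12 lists with LPS (highest other 16) and 14 of 35 the 8 with dexamethasone (14). In footprints 67 and 50 of 100 gave 12 and 9 (19 and 18), and in TE 90 and 80 gave 7 and 5 (16 and 15). Splits that keep most libraries of a treatment together carry part of its effect, so the even ones, which mix the treatments as far as the group size allows, were counted apart. In RNA 0 of 18 even splits gave the 12 lists with LPS (highest 7), so the count of 15 does not show whether chance can be excluded there, and 2 of 18 gave the 8 with dexamethasone. In footprints 49 of 80 and 33 of 79 even splits gave as many lists and in TE 38 of 46 and 25 of 38, so chance is not excluded for these counts or for the 8. For single called lists the splits were counted that gave as small a p. In RNA only the real split did so for cytokines, NF-kB, interferon, inflammasome and ribosome biogenesis with LPS and for glucocorticoid targets, cytokines, NF-kB, interferon and inflammasome with dexamethasone. For the other RNA lists the counts of 35 with LPS were 3 for MAPK phosphatases and for cell cycle, 6 for antigen presentation and for heat shock, 7 for initiation, 9 for other TOP mRNAs and 22 for ribosomal proteins. With dexamethasone they were 7 for biogenesis, 11 for antigen presentation and 17 for the respiratory chain.

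In footprints only the real split of 100 gave as small a p for cytokines, NF-kB, inflammasome, other TOP mRNAs and biogenesis with LPS, and for glucocorticoid targets and inflammasome with dexamethasone. The other counts with LPS were 3 for heat shock, 8 for ribosomal proteins, 14 for interferon, 18 for MAPK phosphatases, 25 for histones, 28 for cell cycle and 30 for AU-rich element factors. With dexamethasone they were 2 for NF-kB and for interferon, 5 for heat shock, 6 for ribosomal proteins, 8 for other TOP mRNAs, 13 for biogenesis and 27 for cytokines. In TE with LPS they were 1 for Toll-like receptor signalling, 4 for other TOP mRNAs, 21 for ribosomal proteins, 23 for phagocytic receptors, 44 for interferon, 46 for NF-kB and 52 for mitochondrial ribosomal proteins. In TE with dexamethasone they were 1 for ribosomal proteins and for the respiratory chain, 2 for other TOP mRNAs, 6 for mitochondrially encoded mRNAs and 16 for mitochondrial ribosomal proteins.

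Even splits reached some of these lists. In RNA they were heat shock (1 of 18) and ribosomal proteins (12) with LPS, and antigen presentation (4) and the respiratory chain (9) with dexamethasone. In footprints they were interferon (9 of 80), MAPK phosphatases (13), histones (15), cell cycle (20) and AU-rich element factors (22) with LPS, and biogenesis (8 of 79) and cytokines (23) with dexamethasone. In TE they were interferon (3 of 46), ribosomal proteins (6), NF-kB (9), phagocytic receptors (12) and mitochondrial ribosomal proteins (31) with LPS, and mitochondrially encoded mRNAs (2 of 38) and mitochondrial ribosomal proteins (7) with dexamethasone. Chance is not excluded for these lists, and for lists that only uneven splits reached, 5 or more of 100 or 2 or more of 35, the splits do not show whether it can be.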
